A study of Mus musculus with 6 samples.

How the data were processed

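The series measured RNA in inguinal white adipose tissue, the subcutaneous fat pad of the groin, from mice aged 20 months. It compared 3 wild-type (WT) samples with 3 samples from mice lacking GSNOR, the S-nitrosoglutathione reductase encoded by Adh5, all on the C57BL/6J background. Per the labels' protocols, RNA was extracted from frozen tissue, messenger RNA was captured on poly-T beads, and random-primed Illumina libraries were made. The labels number the samples 1 to 3 in each group and do not say in so many words that each came from its own animal, so the p-values measure the spread between these samples.

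The authors deposited 1 table of 22695 rows with raw counts and FPKM for each library. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool and whether counting used strand are not given in the sources used here, so overlapping and antisense genes and near-identical gene copies may share counts. The counts were deposited as whole numbers with no normalization, per the file headers and the values. Among the 17 largest counts 11 end in 0 and 6 do not, so some of them may have been rounded. The table holds 1052 rows of gene models added by the authors, with 0.232 to 0.783% of the counts of a library, and 73 rows of genes split into numbered parts, with at most 0.036%. The FPKM values, scaled by the authors to transcript length and to a library size, per the file headers, were used only for 1 alternative. The deposited table also holds the authors' own DESeq comparison as an adjusted p and a log2 fold change per gene.

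Total counts were 22793152, 22360699 and 20277594 in WT replicates 1 to 3 and 21223848, 23961574 and 22884641 in GSNOR KO replicates 1 to 3. A count of 3 corresponded to between 0.125 and 0.148 CPM, the usual unit of counts scaled to the library total. Transcripts of the mitochondrial genome took 28.8 to 37.8% of the counts. No pair of libraries was a duplicate: Pearson correlations of log2(count + 1) across rows, which are not independent replicates, lay between 0.97 and 0.989. Gene coordinates are those of GENCODE release M21 on GRCm38, to which 21261 row identifiers matched.

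Genes were tested with edgeR 4.0.16 (R 4.3.3). The filterByExpr rule kept 13694 genes, TMM factors (0.930 to 1.08) scaled the libraries, and the quasi-likelihood F test with robust dispersion compared GSNOR KO with WT. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are given as log2 of GSNOR KO over WT, and their standard error (SE) is the fold change divided by the square root of F. Values per group are CPM as mean ± SD with n = 3. An exact permutation test of a single value cannot go below 0.10 with 3 against 3 samples, so single values were judged only by the model fitted across genes.

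Before the data were examined, 38 gene lists for adipose function, mitochondria, autophagy, GSNOR-related enzymes and the cell types a fat pad may hold were written down, with 745 entries. Of these, 704 matched by symbol, 13 by identifier and 28 did not match. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, adjusted over the 35 lists tested. Camera compares the mean test statistic of the list members with that of the other genes, so its direction is relative to the other genes. Where a list is said to rank higher or lower, or a rank direction is given, this comparison is meant and not a test on ranks. The sex-linked genes and the chromosome 3 neighbours of Adh5 served as checks. Beside camera stand its result with an estimated correlation, the fry test of whether members move on balance one way, and the number of members called over all genes and adjusted over the list alone. A list score is the mean log2 CPM of the members about its mean over the 6 libraries.

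The rule for named genes was also fixed before the data were examined. It took Adh5, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 members with the smallest p in each list, and Becn1, Ucp1, Lep, Adipoq, Pparg, Ppargc1a, Fasn, Pnpla2 and Lipe, as well as the sex-linked genes and the called neighbours of Adh5. Predicted gene models were left out of the largest changes. Genes named outside the rule are marked as chosen after their values were seen. The single-gene result of the senescence list is not reported here.

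The alternatives fixed beforehand were RLE size factors, library totals only, no filter, a stricter filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, no robust dispersion, the replicate number as a block, and leaving out each library in turn. For the lists they were the estimated correlation, fry, prior counts of 1 and 10, RLE size factors, no filter, the block and the leave-outs. Chosen after seeing the data were offsets for GC content and transcript length, the skeletal muscle score as a covariate, limma on log2(FPKM + 1), a fit without added gene models and numbered parts, windows about Adh5 with and without numbered parts, the list tests without Adh5, and a one-sided Fisher's exact test of pathway names in the deposited table.

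The test was tried on simulated data with the means, dispersions and library sizes of the 13694 genes. In the simulated comparison of GSNOR KO with WT, 55% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold were recovered, with 14 false calls. A simulated list of 20 genes shifted 1.5-fold was called by camera, with the preset and with the estimated correlation, and by fry. Of 20 unshifted lists, camera with the preset correlation called 1, fry called 1 and camera with the estimated correlation called 0. The simulated genes were drawn independently of each other. Estimated correlations within the real lists ran from -0.044 (insulin and glucose) to 0.944 (interferon). The simulated list results therefore do not carry over to real lists whose members move together.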

Results

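Messenger RNA was sequenced from inguinal white adipose tissue of mice aged 20 months, in 3 WT and 3 GSNOR KO samples. The comparison asks which transcripts differ in the fat of old mice without GSNOR, in which the submitters describe enhanced lipid metabolism. GSNOR reduces S-nitrosoglutathione, a carrier of nitric oxide groups, and its gene is Adh5. The libraries held 20277594 to 23961574 counts, and 13694 genes were tested.

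Adh5, the targeted gene (ENSMUSG00000028138, chromosome 3, 138443093 to 138455499, GRCm38), was lower in all 3 GSNOR KO libraries. Its level was 76.9, 66.4 and 58.8 CPM in WT replicates 1 to 3 and 4, 3.81 and 5.08 CPM in GSNOR KO replicates 1 to 3. The means were 67.4 ± 9.08 and 4.30 ± 0.683 CPM (SD, n = 3 each), a log2 fold change of -3.97 (SE 0.171, edgeR adjusted p = 0.000135). The labels and the Adh5 counts go together in every library.

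**Figure D1:**
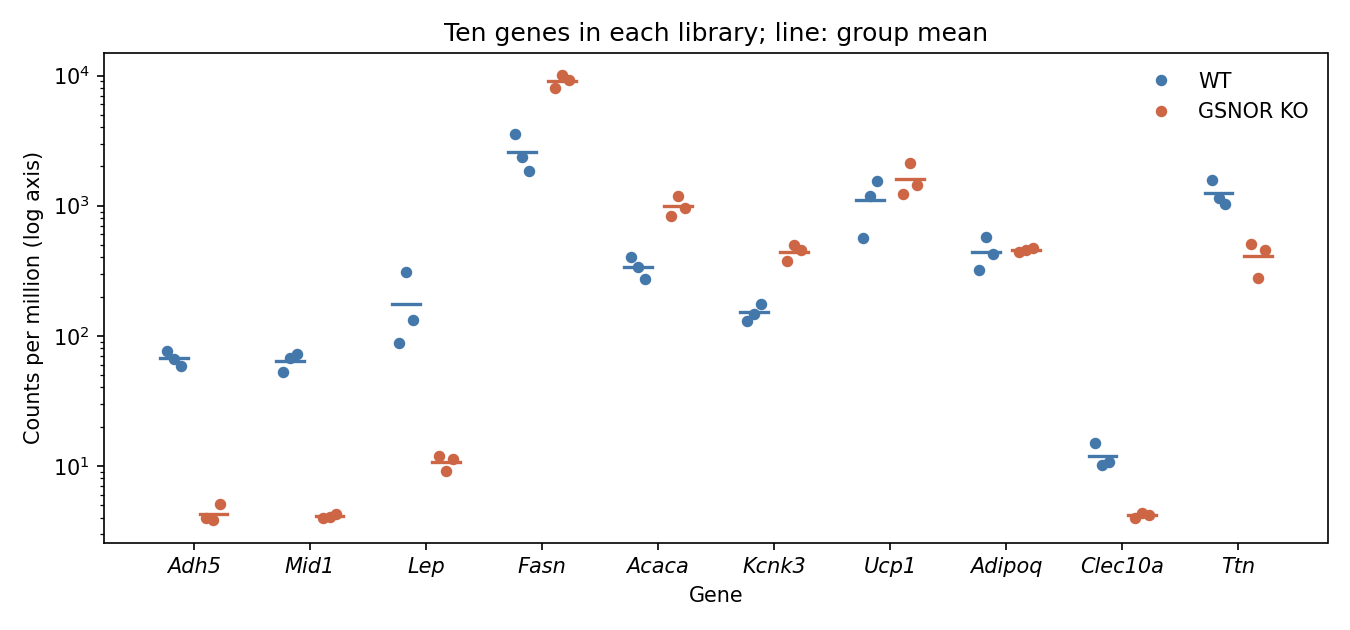
CPM on a log axis for 10 genes in each of the 6 libraries, with points for libraries and lines for group means. Adh5 lay at 58.8 to 76.9 CPM in WT and 3.81 to 5.08 CPM in GSNOR KO, and the groups overlapped for Ucp1 and Adipoq.

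Across the transcriptome 964 of 13694 genes were called, 534 higher and 430 lower in GSNOR KO, and 433 of them differed at least 2-fold, 152 higher and 281 lower. With library totals as the only scaling the split was 314 higher and 406 lower. In all 964 called genes the 3 GSNOR KO libraries lay on one side of the 3 WT libraries, as in 36.7% of all tested genes. Calling a gene itself favours such separation. Of all orderings of the libraries 10% separate the groups, but genes move together, so this comparison of shares is no test. The count of calls changed with single libraries: it was 13 without WT replicate 2, 5 without GSNOR KO replicate 1, 3 without GSNOR KO replicate 2 or 3, 915 without WT replicate 3 and 2844 without WT replicate 1. The folds changed less: 913 of the 964 genes stayed within 1.5 times their fold in every leave-out, and 36 moved further without WT replicate 1. These genes were chosen on the same libraries, which favours stable folds, and their median absolute log2 fold change was 0.913. Only 3 genes were called in all 6 leave-outs: Adh5, Mid1 and a numbered part of Gbp2b. Each other gene named as risen or fallen lost its call in at least 1 leave-out. Of 85 called genes named by the rule or after their values were seen, 79 kept the call in at most 2 leave-outs.

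**Figure D2:**
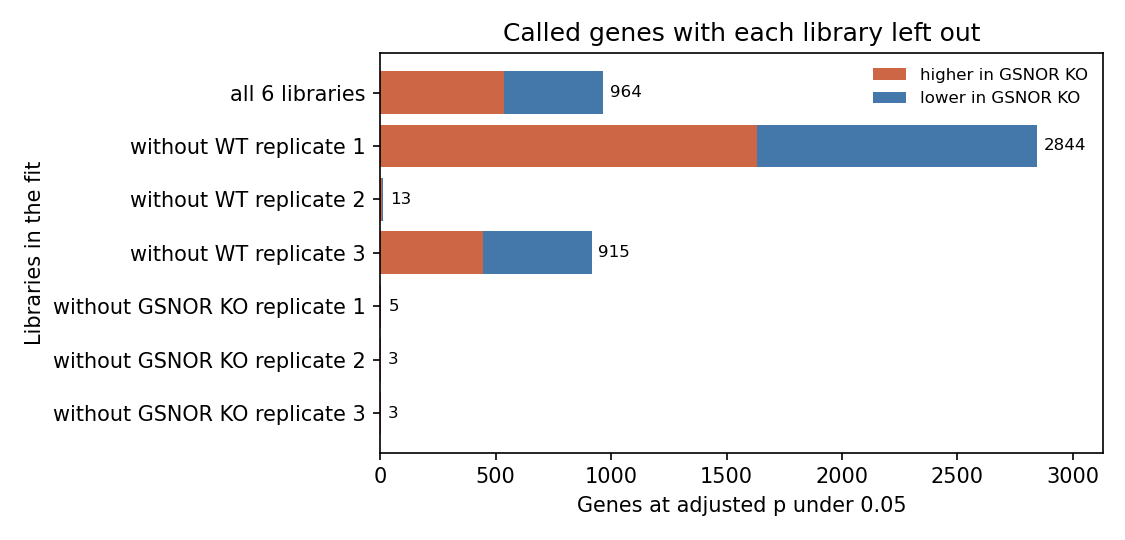
Number of genes at an adjusted p under 0.05 with all 6 libraries and with each library left out, as bars divided into genes higher and lower in GSNOR KO. The count was 964 with all libraries and between 3 and 2844 with 1 library left out.

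Genes of fatty acid synthesis were higher in GSNOR KO. Of 19 tested members of the de novo lipogenesis list 12 rose, 0 fell and 7 did not pass, and 15 rose when adjusted over the list alone. Fasn, the fatty acid synthase, rose from 2586 ± 885 to 9104 ± 1001 CPM (SD, n = 3 each, log2 fold change 1.82, SE 0.251, adjusted p = 0.0189). Acaca, which makes malonyl-CoA for that enzyme, rose from 337.1 ± 64.9 to 995.2 ± 177 CPM (log2 fold change 1.56). Slc25a1, the mitochondrial citrate carrier, rose 2.52-fold, Thrsp, a lipogenic regulator, rose 2.75-fold and Acss2, which activates acetate, rose 1.87-fold. The list had a median log2 fold change of 0.78 and passed camera (adjusted p = 5.59e-10) and fry (adjusted p = 0.0182). The adjusted p was 0.528 with an estimated correlation. The list passed camera in all 6 leave-outs, and its score lay between -0.56 and -0.40 in WT and between 0.30 and 0.63 in GSNOR KO.

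In the triglyceride synthesis list 3 of 17 members rose and 0 fell: Dgat1, which adds the last acyl chain, rose 1.95-fold, Mogat1 rose 2.19-fold and Agpat6 (also called Gpat4) rose 1.86-fold. Adjusted over the list alone 9 rose and 1 fell. The median was 0.40 (camera adjusted p = 0.00103, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). Of 17 lipolysis genes 1 rose, Pnpla2, the adipose triglyceride lipase, from 1816 ± 122 to 2613 ± 56.8 CPM (log2 fold change 0.53, adjusted p = 0.0428), and 2 rose when adjusted over the list alone. Lipe, the hormone-sensitive lipase, had a log2 fold change of 0.45 (adjusted p = 0.0602). The lipolysis list had a median of 0.25 (camera adjusted p = 0.0228, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). The triglyceride and lipolysis lists both lost their camera call with the skeletal muscle score as covariate.

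Of 49 nuclear genes of the respiratory chain 9 rose, 0 fell and 40 did not pass, and 20 rose and 1 fell when adjusted over the list alone. Cox6a1 rose from 1314 ± 30.3 to 2214 ± 165 CPM, Ndufa1 rose 1.63-fold, Cox8a rose with a log2 fold change of 0.68 and Uqcrq rose 1.63-fold. The median was 0.29 (camera adjusted p = 7.53e-09, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). Of the 10 tested mitochondrially encoded genes 0 were called by edgeR, DESeq2 or limma voom and 0 lay at an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.905), with mt-Co2 at a log2 fold change of 0.21 and mt-Nd5 at -0.44. In the fatty acid oxidation list 4 of 26 members rose, 0 fell and 7 rose when adjusted over the list alone. Ehhadh, a peroxisomal enzyme, rose 2.29-fold, Acsl5 rose 2.82-fold, Etfb rose 1.62-fold and Acadvl rose 1.41-fold (median 0.23, camera adjusted p = 0.00221, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation).

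Of 23 brown and beige adipocyte genes 5 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. Kcnk3, a potassium channel, rose from 151.0 ± 23.6 to 442.3 ± 59.9 CPM (log2 fold change 1.55, SE 0.165, adjusted p = 0.0178). Elovl3 rose 2.91-fold, Slc27a2 rose 2.45-fold and Cidea, a lipid droplet protein, rose 1.68-fold. Ucp1, the uncoupling protein of thermogenic fat, was at 1098 ± 493 CPM in WT and 1591 ± 463 CPM in GSNOR KO (log2 fold change 0.54, SE 0.368, adjusted p = 0.380), with overlapping libraries. Ppargc1a had a log2 fold change of -0.25 (adjusted p = 0.391). Ucp1 lay above Adipoq in all 6 libraries, the depot is known from the labels alone, and no other depot was analysed here. The list median was 0.35 (camera adjusted p = 0.00615, fry adjusted p = 0.0522, adjusted p = 0.528 with an estimated correlation). With the skeletal muscle score as covariate the list lost its camera call and the log2 fold change of Ucp1 was -0.725. In the creatine and calcium cycling list 1 of 8 members, the calcium pump gene Atp2a2, fell (log2 fold change -1.30, and -0.45 with adjusted p = 0.243 with the skeletal muscle score as covariate), and adjusted over the list alone 2 rose and 2 fell (median -0.24, camera adjusted p = 0.677). Atp2a2 was at 679, 422 and 317 CPM in WT replicates 1 to 3, and the skeletal muscle genes were also highest in WT replicate 1.

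The white adipocyte list ranked lower in GSNOR KO, in libraries whose depot is known from the labels alone. Lep, which encodes leptin (chromosome 6, 29060220 to 29073877), fell from 176.5 ± 118 to 10.8 ± 1.52 CPM (SD, n = 3 each, log2 fold change -4.03, SE 0.484, adjusted p = 0.0181), 16.4-fold higher in WT and 10.1-fold without WT replicate 2 (log2 fold change -3.34). Nnat, an imprinted proteolipid, had a log2 fold change of -3.57 (-2.78 without WT replicate 2) and Sncg, the gamma-synuclein gene, one of -1.36, and both fell. In this list 3 of 13 members fell, 0 rose and 7 fell when adjusted over the list alone (median -0.77, camera adjusted p = 0.00207, fry adjusted p = 0.100, adjusted p = 0.528 with an estimated correlation). Of 20 mature adipocyte genes 1 rose, Slc36a2, and 1 fell, Car3, while 4 rose and 1 fell when adjusted over the list alone (median 0.12, camera adjusted p = 0.099, from 0.0156 without WT replicate 2 to 0.356 without WT replicate 1). Adipoq, which encodes adiponectin, was at 440.9 ± 128 and 454.6 ± 16.1 CPM (log2 fold change 0.04, adjusted p = 0.909), with the sign of this value turning to -0.002 with library totals only, and Pparg had a log2 fold change of -0.18 (adjusted p = 0.430).

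The lists of adipose progenitors and fibroblasts and of the extracellular matrix ranked lower in GSNOR KO. In the progenitor list 4 of 16 members fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone. Pdgfra, a progenitor receptor, fell from 18.2 ± 0.867 to 8.91 ± 1.22 CPM, Thy1 had a log2 fold change of -1.07, and Lum and Dcn, small proteoglycans, had log2 fold changes of -1.04 and -0.89 (list median -0.73, camera adjusted p = 0.0016, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). In the matrix list 4 of 27 members fell, 0 rose and 9 fell when adjusted over the list alone. Lox, a collagen cross-linking enzyme, fell from 29.9 ± 9.33 to 11.6 ± 0.795 CPM, and Col1a2, Col5a2 and Mmp2 fell with log2 fold changes of -0.98, -0.87 and -0.74 (list median -0.47, camera adjusted p = 0.000904, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation).

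The macrophage and skeletal muscle lists ranked lower in GSNOR KO, and WT replicate 1 was the library highest in both. Of 20 macrophage genes 8 fell, 0 rose and 16 fell when adjusted over the list alone. The lectin gene Clec10a fell from 11.95 ± 2.66 to 4.16 ± 0.153 CPM, the complement gene C1qc from 31.0 ± 4.69 to 15.3 ± 0.566 CPM, and the mannose receptor gene Mrc1 and Gpnmb had log2 fold changes of -1.30 and -2.44 (list median -1.43, camera adjusted p = 5.75e-07, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). Of 20 skeletal muscle genes 7 fell, 0 rose and 19 fell when adjusted over the list alone. Ttn, the titin gene, fell from 1249 ± 285 to 412.0 ± 119 CPM, and Neb, Ryr1 and Atp2a1 had log2 fold changes of -1.67, -1.45 and -1.66 (list median -1.42, camera adjusted p = 1.42e-07, fry adjusted p = 0.100, adjusted p = 0.528 with an estimated correlation). The muscle genes took 4.88, 1.90 and 2.13% of the counts in WT replicates 1 to 3 and 1.32, 0.77 and 1.15% in GSNOR KO replicates 1 to 3. Both lists passed camera in all 6 leave-outs. The macrophage list lost its camera call with the skeletal muscle score as covariate.

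**Figure D3:**
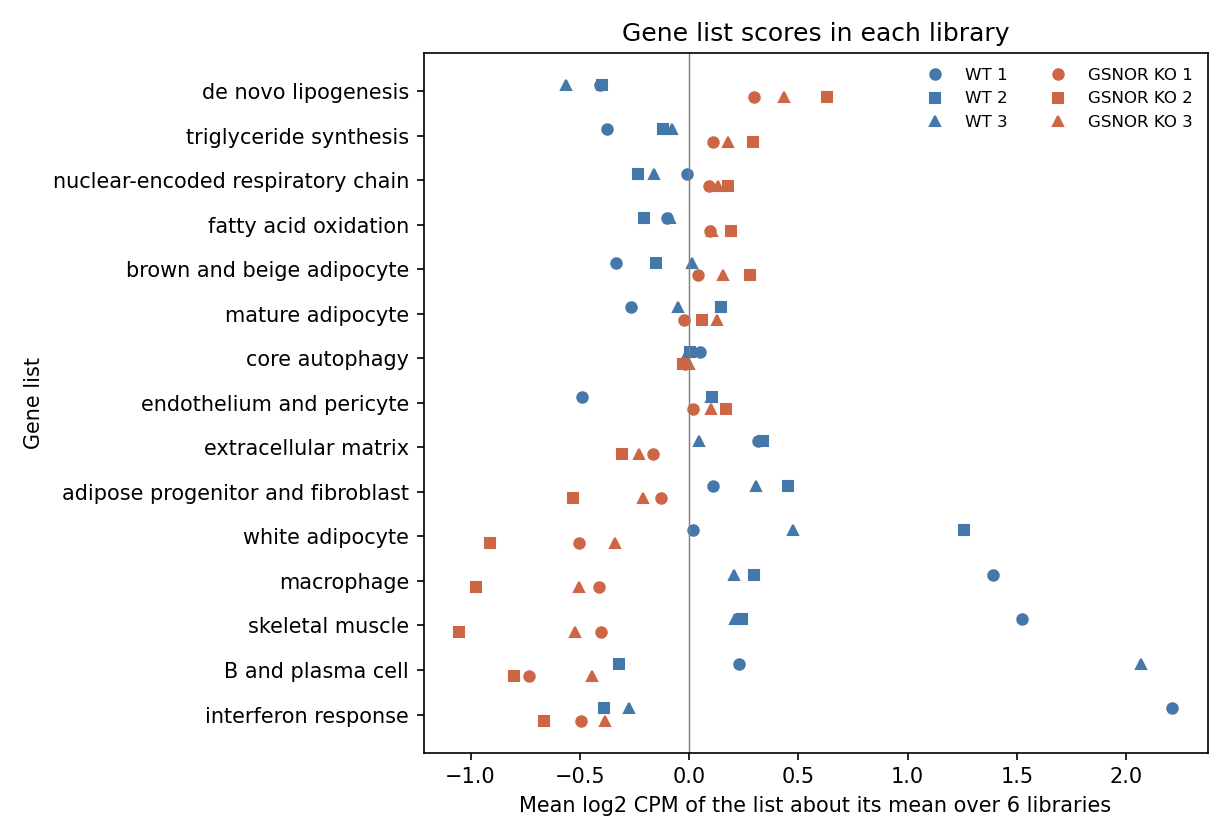
Score of 15 gene lists in each library, as the mean log2 CPM of the members about its mean over the 6 libraries, with color for the group and shape for the replicate. De novo lipogenesis lay between -0.56 and -0.40 in WT and between 0.30 and 0.63 in GSNOR KO, while the interferon response lay at 2.21 in WT replicate 1 and between -0.67 and -0.27 in the other libraries.

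In 4 of the other 6 immune lists the camera call was lost without 1 WT library. The interferon list (1 of 18 members fell, Oas2, 0 adjusted over the list alone, median -1.49) scored 2.21 in WT replicate 1 and -0.39 and -0.27 in WT replicates 2 and 3, and its camera adjusted p went from 0.00945 to 0.457 without WT replicate 1. The inflammatory cytokine list had 0 of 16 members called by edgeR, also adjusted over the list alone, 7 at an unadjusted p under 0.05 and 1 called by DESeq2 (median -1.88), with the chemokine gene Ccl7 at a log2 fold change of -4.21 (adjusted p = 0.134). Its camera adjusted p went from 0.0184 to 0.286 without it. The neutrophil and mast cell list (1 of 8 fell, the tryptase gene Tpsb2, 2 adjusted over the list alone, median -1.28) went from 0.0222 to 0.138 without it. The B and plasma cell list (0 of 11 called by edgeR, 7 at an unadjusted p under 0.05, 7 called by DESeq2, 7 that fell when adjusted over the list alone, median -1.77) scored 2.07 in WT replicate 3, and its adjusted p went from 0.0097 to 0.0549 without that library. The T and NK cell list (1 of 12 fell, Thy1, also adjusted over the list alone, median -1.22, camera adjusted p = 0.00235) and the MHC class II list (2 of 8 fell, H2-Aa and H2-Ab1, 5 adjusted over the list alone, median -1.15, camera adjusted p = 0.00214) passed in all 6 leave-outs, and scored 1.30 and 1.22 in WT replicate 3 against at most 0.19 in the other WT libraries. Thy1 is also in the progenitor and fibroblast list, so no gene found only in the T and NK list was called. With an estimated correlation the adjusted p was 0.662 for interferon, 0.629 for cytokines, 0.581 for neutrophils and mast cells, 0.599 for B and plasma cells, and 0.528 for T and NK cells and for MHC class II. With fry it was 0.340 for interferon, 0.297 for cytokines, 0.106 for neutrophils and mast cells, 0.290 for B and plasma cells, 0.0974 for T and NK cells and 0.143 for MHC class II. The interferon and cytokine lists turned upward and passed camera with the skeletal muscle score as covariate (adjusted p = 0.000297 and 0.00779). That covariate differs between the groups itself and was highest in WT replicate 1 (1.53, against 0.24 and 0.21 in WT replicates 2 and 3). The cytokine list also scored highest there (2.315). The upward turn therefore cannot be read as a rise with genotype.

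Autophagy genes were examined because the series title names Beclin-1. Becn1, which encodes it, was at 65.8 ± 4.39 CPM in WT and 62.3 ± 3.98 CPM in GSNOR KO (log2 fold change -0.08, SE 0.106, adjusted p = 0.657). Of 31 core autophagy genes Wipi2 and Atg2a, both acting at the forming autophagosome, rose with log2 fold changes of 0.69 and 0.60, and Ulk2, an initiating kinase, fell by 0.58 on the log2 scale. Adjusted over the list alone 2 rose and 2 fell (list median -0.04, camera adjusted p = 0.908). Of 16 mitophagy genes 0 were called by edgeR, also adjusted over the list alone, 2 lay at an unadjusted p under 0.05 and DESeq2 called 1 (median -0.11, camera adjusted p = 0.514). Of 24 lysosomal genes 3 fell, Ctsk, Atp6v0d2 and Ctss, and 3 fell when adjusted over the list alone (median -0.16, camera adjusted p = 0.0612). It passed camera without WT replicate 2 or 3 (adjusted p = 0.0239 and 0.011) and in 0 of the other leave-outs, with 0.751 without WT replicate 1. Its score was 0.56 in WT replicate 1 and 0.11 and -0.02 in WT replicates 2 and 3, and Ctss was at 105.9 CPM in WT replicate 1 and at 23.3 and 21.5 CPM in those. Ctsk and Ctss encode cathepsins.

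Among enzymes related to GSNOR, the alcohol and aldehyde dehydrogenase list had 3 of 15 members that fell, Adh5, Adh1 and Aldh1a1, and 3 rose and 3 fell when adjusted over the list alone (median -0.35, camera adjusted p = 0.115, fry adjusted p = 0.0386, adjusted p = 0.599 with an estimated correlation). Without Adh5 itself the list no longer passed fry (adjusted p = 0.225). Aldh1a1, a retinaldehyde dehydrogenase, had a log2 fold change of -1.74. In the glutathione, thioredoxin and NRF2 list 2 of 28 members rose, Sod1 and Gpx4, with log2 fold changes of 0.63 and 0.55, and 2 rose when adjusted over the list alone (median -0.08, camera direction up, adjusted p = 0.908). In the nitric oxide list 1 of 16 members rose, Asl, which makes arginine (log2 fold change 0.60), also when adjusted over the list alone (median -0.02, camera adjusted p = 0.76). In the insulin and glucose list Pdk1 rose and Enpp1 fell among 19 members, and 1 rose and 1 fell when adjusted over the list alone (median -0.19, camera adjusted p = 0.115, fry adjusted p = 0.0182, adjusted p = 0.528 with an estimated correlation).

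The endothelium and pericyte list ranked higher in GSNOR KO (median 0.23, camera adjusted p = 0.0457, fry adjusted p = 0.430, adjusted p = 0.662 with an estimated correlation), yet its 1 called member of 17, Prox1, a lymphatic regulator, fell, as it did adjusted over the list alone, and the camera adjusted p was 0.403 without WT replicate 1, 0.0801 without GSNOR KO replicate 2 and 0.0582 without GSNOR KO replicate 3. The senescence list of 12 tested members ranked lower (median -0.37, camera adjusted p = 0.0387, fry adjusted p = 0.0386, adjusted p = 0.528 with an estimated correlation). The immediate early and heat shock list had 1 of 18, Fos, from 29.9 ± 4.58 to 9.36 ± 1.67 CPM, and 5 fell when adjusted over the list alone (median -0.50, camera adjusted p = 0.015, fry adjusted p = 0.0438, adjusted p = 0.528 with an estimated correlation). The unfolded protein response list had 0 of 20 called by edgeR, 8 at an unadjusted p under 0.05 and 5 called by DESeq2, with 2 that rose and 3 that fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.0367, fry adjusted p = 0.173, adjusted p = 0.599 with an estimated correlation). Without WT replicate 1 these 3 lists no longer passed camera (adjusted p = 0.0967, 0.127 and 0.393). The senescence list was also lost without GSNOR KO replicate 1 (0.0925) or 2 (0.0555), and so was the unfolded protein response list (0.0843 and 0.0758). In the cell cycle list Mki67 fell among 16 members, 1 adjusted over the list alone (median -0.27, adjusted p = 0.162) and in the circadian list Bhlhe41 fell among 16, 2 adjusted over the list alone (median -0.20, adjusted p = 0.168, from 0.0415 without GSNOR KO replicate 1 to 0.449 without GSNOR KO replicate 2). Of 12 nerve and Schwann cell genes and 5 erythroid genes 0 were called by edgeR, DESeq2 or limma voom, with 1 and 0 at an unadjusted p under 0.05 (medians -0.16 and 0.12, adjusted p = 0.971 and 0.379, with camera ranking nerve genes up against their median). Of 4 tested epithelial and mammary genes, too few for a list test, Krt7 rose from 0.120 ± 0.0247 to 1.62 ± 0.316 CPM.

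The largest rises under the naming rule were in Slc2a5, a fructose transporter (7.61-fold, from 1.13 ± 0.301 to 8.63 ± 1.58 CPM), Tjp3 (7.49-fold), Xlr3b (6.43-fold), Ngef (6.33-fold), Mfsd2a, a lipid transporter (6.10-fold), Ttc25 (6.05-fold), Aspg, an asparaginase (5.41-fold, from 134.4 ± 47.2 to 727.1 ± 229 CPM) and Tfr2, a transferrin receptor (5.35-fold). The largest falls were in Lep, Mid1, Adh5, Wisp2 (log2 fold change -3.58), Nnat, Rgs1 (-3.25), Fgfbp1 (-3.20) and Ctss (-3.10). Single WT libraries set part of these folds: the log2 fold change was -2.28 for Wisp2 without WT replicate 2, and without WT replicate 1 it was -2.47 for Rgs1, -2.34 for Fgfbp1 and -1.90 for Ctss. Mid1, a ubiquitin ligase gene (X chromosome, 169685199 to 170005736), fell from 64.1 ± 10.7 to 4.09 ± 0.120 CPM (log2 fold change -3.97, SE 0.163, adjusted p = 0.000135). Part 3 of Gbp2b (gene on chromosome 3, 142594847 to 142619179), named after its values were seen, had 1, 5 and 3 counts in WT and 677, 798 and 720 counts in GSNOR KO (adjusted p = 0.000135), while part 2 had 776, 586 and 527 against 494, 485 and 449 counts (adjusted p = 0.121). Gbp2b has close paralogs, so its counts are uncertain.

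Near Adh5 on chromosome 3, 14 listed neighbours were tested. Adh1 fell (log2 fold change -1.10) and Dapp1 fell from 3.81 ± 0.490 to 0.719 ± 0.357 CPM (-2.40), while Trmt10a (1.09) and Mttp, a lipid transfer protein (0.92), rose, and 2 rose and 4 fell when adjusted over the list alone. The spans of Mttp (138089854 to 138144968) and Trmt10a (138143448 to 138159821) overlap, so these genes may share counts. All 4 tested Y-linked genes, Ddx3y, Uty, Eif2s3y and Kdm5d, were detected in both groups and 0 were called by edgeR, 1 by DESeq2 and 1 when adjusted over the list alone, the log2 fold changes lying between -0.72 and -0.28. The authors' deposited table calls 136 genes at its thresholds of adjusted p 0.01 and fold 2, 95 higher and 41 lower in GSNOR KO, and 128 of these were called here with the same sign.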

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

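The GC and length offsets, the muscle covariate, the FPKM fit and the fit without unnamed features were chosen after seeing the data. The log2 fold change of Adh5 lay between -4.10 and -3.18 and stayed called in every setting run. The 964 calls became 2300 with DESeq2, 199 with limma on log2 FPKM and 405 with the muscle score as covariate, and ranged from 3 to 2844 over the leave-outs. The 433 calls of at least 2-fold became 1025, 86 and 203 in those 3 settings and ranged from 3 to 600 over the leave-outs. Removing a library leaves fewer samples, but leaving out WT replicate 1 raised the count, and the cause was not tested. By log2(count + 1), WT replicate 1 correlated at 0.982 and 0.981 with WT replicates 2 and 3, which correlated at 0.989 with each other. The replicate numbers do not pair the samples: deviations from the group means correlated at 0.159, 0.137 and -0.059 between samples of the same number, and GSNOR KO replicate 3 correlated best with WT replicate 1 (0.082). With the replicate block 884 genes were called, 559 of them at least 2-fold, and 638 were shared with the 964. The block left Adh5 called and 21 lists called. With GC and length offsets 739 genes were called, 613 of them shared.

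The 21 lists called by camera became 0 with an estimated correlation (1 list at an unadjusted p under 0.05), 12 with fry and 13 with the muscle score as covariate, and ranged from 14 to 23 over the leave-outs. With that covariate, which differs between the groups itself and fixes the muscle list by construction, the de novo lipogenesis list kept a mean of 0.86, while the brown and beige, triglyceride, lipolysis, macrophage, senescence and immediate early lists lost their calls. Under it the log2 fold change took the other sign for Ckmt2 (0.13), Cd63 (0.12), Zbp1 (1.097), Vdac1 (0.066), Gbp2 (0.10), Spp1 (1.38), Kdr (-0.10), Eng (-0.089), Nqo1 (0.18), Ccl7 (3.25), Cxcl10 (2.11), Arntl (-0.27), Trp63 (0.35), Cldn5 (-0.22), Gfra3 (-0.28), Prlr (0.28), Pmp2 (1.24), mt-Co2 (-0.085), mt-Co3 (-0.12), Hba-a2 (-0.33), Hba-a1 (-0.44), Hbb-bs (-0.27), Ucp1 (-0.72), Becn1 (0.11), Adipoq (-0.46), Mx1 (3.66). Of these, Ccl7, Cxcl10 and Mx1 were then called (adjusted p = 0.039, 0.0477 and 0.0258). The direction in which camera ranked the list also turned for these lists, given with their mean log2 difference: creatine and calcium cycling (-0.026), mature adipocyte (-0.16), mitochondrially encoded (-0.32), core autophagy (0.016), mitophagy (0.052), lysosome (0.05), alcohol and aldehyde dehydrogenases (-0.26), neutrophil and mast cell (-0.077), inflammatory cytokines (1.05), interferon response (1.17), endothelium and pericyte (-0.35), skeletal muscle (0), nerve and Schwann cell (-0.17), erythroid (-0.31), unfolded protein response (0.10). The mean itself kept its sign for the creatine, mitochondrially encoded, dehydrogenase, neutrophil and nerve lists. Among the lists that turned, the cytokine and interferon lists passed camera upward (adjusted p = 0.00779 and 0.000297) and the endothelium list downward (0.0229). The muscle score was highest in WT replicate 1 (1.53), the library that was also highest in the cytokine and interferon scores and in Mx1. Such turns therefore do not show a change with genotype. The cause of these changes was not tested.

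Other changes of sign were in values that were not called. Adipoq was at -0.002 with library totals only, and Cdh1 at -0.40 with limma voom and -0.018 with the replicate block. With GC and length offsets mt-Nd2 was at 0.027, Hba-a2 at -0.084, Hba-a1 at -0.048 and Becn1 at 0.047, and camera's rank direction turned for core autophagy (mean -0.001) and nerve and Schwann cell (-0.059). The direction, but not the sign of the mean, also turned for the nerve and Schwann cell list with fry and the replicate block (-0.045) and RLE size factors (-0.028), and for core autophagy with no filter (-0.028). Over the leave-outs the log2 fold change ran for Hba-a1 from -0.002 to 0.39, Hbb-bs from -0.026 to 0.31, Becn1 from -0.12 to 0.004, Adipoq from -0.11 to 0.29, Mx1 from -4.87 to 0.12 (0.12 without WT replicate 1, the library with 773 of its counts), Cdh1 from -0.51 to 0.73. Where the rank direction turned in a leave-out, the list means ran for mitochondrially encoded from -0.089 to 0.15, core autophagy from -0.036 to 0.015, nerve and Schwann cell from -0.20 to 0.13, glutathione, thioredoxin and NRF2 targets from -0.11 to 0.067. The cause was not tested.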

Other observations

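The pathway, GC and adipocyte-share tests, the endothelium test, the test without WT replicate 1 and the test near Adh5 were chosen after the data were seen, while the splits of the libraries were planned. Pathway names in the deposited table gave a second view, which overlaps the fixed lists in part. Among 263 pathways and 4739 tested genes with a pathway, 11 were enriched among genes higher in GSNOR KO and 14 among genes lower, by one-sided Fisher's exact tests adjusted per direction. Biosynthesis of amino acids held 11 higher genes where 2.6 were expected (adjusted p = 0.00385), Peroxisome 12 where 3.1 were expected (adjusted p = 0.00385), and Oxidative phosphorylation 15 where 5.2 were expected (adjusted p = 0.0111). Complement and coagulation cascades held 10 lower genes where 1.4 were expected (adjusted p = 7.87e-05), and Circadian rhythm held 5 where 1.0 was expected (adjusted p = 0.0471). The fixed circadian list did not pass camera (adjusted p = 0.168), with 1 of 16 members called. Genes in a pathway are not independent of each other. The enrichments rest on the called genes, whose number ranged from 3 to 2844 over the leave-outs.

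Ucp1 lay above Adipoq in all 6 libraries named as inguinal white fat. Ucp1 was at 1098 CPM in WT and 1591 CPM in GSNOR KO, and Adipoq at 440.9 and 454.6 CPM. Of 2 further genes chosen after their values were seen, Zic1 lay between 4.08 and 6.17 CPM and Lhx8 between 0.90 and 3.86 CPM. Zic1 belongs to the brown and beige adipocyte list. No other fat depot was analysed here, so whether these levels are high for the named depot, and whether the depot is as named, is left open. This doubt bears on the white and the brown adipocyte lists, and on the rise of the lipogenesis list described below. Mx1, also chosen after its values were seen, was at 33.8 CPM in WT replicate 1 and at most 0.90 CPM in the other libraries. Gm5900 had 0 counts in all WT libraries and 71, 59 and 93 in GSNOR KO, and Gm15446 had 1, 0 and 2 against 98, 42 and 67 counts.

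The first pattern is the rise of the de novo lipogenesis list, a mean log2 difference of 0.91 with a pooled SD between libraries of 0.136. Fold changes rose with GC content across genes (Pearson r = 0.216 over 13042 genes, which are not independent), and genes higher in GSNOR KO had a median GC of 55.3% against 48.0% for genes lower. Removing the GC and length trend, which took r to 0.015 and moved members by -0.16 to 0.17, left the difference at 0.911, which argues against that trend as the cause. A larger share of adipocytes would raise the mature adipocyte list alike, but the lipogenesis score minus that score still differed by 0.798 (pooled SD 0.191). That list was not built to tell brown from white adipocytes, so a different mix of these stays open, untested. Between groups the brown and beige score differed by 0.316 and the white adipocyte score by -1.172. The loss of GSNOR, feeding state and other differences between the animals stay open, untested, and a biological change may underlie the pattern only as a hypothesis.

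The second pattern is the fall of the macrophage and skeletal muscle lists, a mean log2 difference of -1.29 with a pooled SD of 0.548. It was -1.291 after removing the GC and length trend and -0.853 without WT replicate 1, both of which argue against those as the whole cause. With the skeletal muscle score as covariate the macrophage list lost its camera call. A smaller share of every cell type other than adipocytes would lower the endothelium and pericyte list alike, but that list differed by 0.19 (pooled SD 0.249). The difference of the scores was -1.481 between groups (pooled SD 0.791) and -0.876 without WT replicate 1 (pooled SD 0.321). In both cases the libraries of the groups did not overlap. The difference reached the size set for the test only without WT replicate 1, by a rule written after the data were seen. The progenitor and matrix scores also differed, by -0.578 and -0.464. The endothelium list thus did not fall alike, but a single reference list cannot decide on such a share. A change in the endothelium itself, muscle taken along in dissection and a change with genotype stay open, untested.

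The third pattern is the called genes near Adh5. Targeted alleles can carry a flanking segment of another strain, which could alter neighbours such as Dapp1 and Adh1. Within 10 Mb of Adh5, leaving it out, 7 of 78 genes were called (8.97%) against 7.09% elsewhere, a one-sided Fisher's exact p of 0.316, and within 5 Mb 5 of 34 (p = 0.0897). Gbp2b, 4.16 Mb from Adh5, was left out there as a gene in numbered parts, and with each part counted the same exact test gave 6 of 36 within 5 Mb (p = 0.0393) and 8 of 80 within 10 Mb (p = 0.206). Mttp and Trmt10a, whose spans overlap, were counted there as separate genes. The genes are too few and the choice of window matters too much to decide. Mid1 (X chromosome), Gm15446 (chromosome 5) and Gm5900 (chromosome 7) lie on other chromosomes, which these windows do not cover. A strain difference elsewhere in the genome was not tested and stays open. For the count of calls, the 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 964 calls, reached by 1 split, and the highest of the other splits gave 0.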
